A study of Mus musculus with 2 samples.

How the data were processed

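Single-cell RNA sequencing of polyadenylated RNA was done on 2 mouse samples with the BD Rhapsody whole transcriptome kit, 1 library each. The embryoid sample holds aggregates made by joining embryonic stem (ES) cells, which carry a red fluorescent actin marker, with XTE cells. The XTE cells were reprogrammed from ES cells with a fluorescent histone tag at the Gata6 locus and kept in medium with a GSK3 inhibitor, BMP4, Fgf4 with heparin, and Activin. Per the labels, 10000 ES cells and 50000 to 80000 XTE cells were joined, grown for 48 h in aggregation wells and then for 48 h in repellent plates. The blastocyst sample holds whole embryos of embryonic day 4.5. Each library was made from 6000 cells.

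The deposited files give, for each gene symbol and cell barcode, the counts of unique molecular identifiers (UMIs), as raw whole numbers of 1 or more. The submitters' processing notes name bcl2fastq 2.19.1.403, UMI-tools 1.0.1, STAR 2.7.1a, Subread (featureCounts 1.6.4) and the genome build mm10. Their settings, the gene annotation and the rule by which barcodes were called as cells are not given in the sources used here. The embryoid file holds 28923930 UMIs in 5546 barcodes and the blastocyst file 11047555 UMIs in 1288 barcodes.

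The filters, the clustering settings, the marker genes, the gene lists, the rule for named genes and the alternatives that the closing section does not mark as added were set before the data were examined. A barcode was kept with at least 1000 UMIs, at least 500 detected genes and at most 25% of its UMIs from mitochondrial genes, and barcodes that Scrublet (scanpy 1.11.5) called doublets were then removed in each library. Scrublet called 4 embryoid barcodes, or 0.0751%, so the caller in effect did not work in that library. Each library was clustered on its own: counts scaled to the barcode's total, 2000 variable genes without ribosomal genes, mitochondrial genes or members of the gene lists, 30 principal components, a shared nearest neighbour graph with 20 neighbours, and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.0 with seed 1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

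Clusters were named from 87 marker genes of 8 classes, of which 80 matched a symbol in the files. A marker counted as high in a cluster at 20 CPM or more (CPM, the UMIs of a gene scaled to the total of its profile) and at 0.333 or more of its highest level in any cluster. A cluster took the class with the largest share of detected markers high, among classes with at least 3 high markers. It stayed unnamed when its 10 leading genes (ratio with 5 CPM added) held more markers of another class than of its own, when its median mitochondrial share was under 0.1 of the library's median, or when it was shallow (median UMIs under 0.333 of the library's) with no marker among the leading genes. This scoring and the exclusion for low mitochondrial share were written after marker levels had been seen and were revised once, by the minimum of 3 high markers. A version that counted leading markers only at a high level was tried after the alternatives had been run and was not adopted. Names end in -like for that reason: epiblast-like (EPI-like), primitive endoderm-like (PrE-like), trophectoderm-like (TE-like) and fibroblast or extraembryonic mesoderm-like (FIB-like). The other marker classes (primitive streak or mesoderm, blood or maternal leukocyte, neural, 2-cell-like) named no cluster.

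With 1 library per group no p-value, standard error or count of changed genes can be given. UMIs were summed over the cells of a class or cluster and scaled to CPM. Ratios between profiles are log2 ratios after adding 1 CPM to each. Each has an exact 95% interval of the ratio of the counts themselves, without the added CPM, so that for a gene near 0 the ratio can lie outside its interval. Single levels have an exact Poisson 95% interval and shares of cells an exact Clopper-Pearson 95% interval. A ratio against a gene with 0 UMIs is a lower bound against a floor of 3 UMIs over the whole summed profile.

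Genes were tested in 27 lists with 323 members, of which 315 matched. They cover pluripotency (naive; formative and primed), later trophoblast, visceral and parietal endoderm, basement membrane, tight junction and polarity, fluid transport, targets of BMP, Wnt, FGF/ERK and YAP, the Nodal pathway, glycolysis, oxidative phosphorylation, hypoxia, cholesterol synthesis, amino acid stress, p53 targets, dissociation stress, S phase, G2/M phase, lysosome, imprinted genes by parental origin, DNA methylation, and interferon with MHC class I. For each list the median log2 ratio over its measured members is given, with its percentile among 10000 random lists of equal size matched on mean expression in 20 bins. Where a member had 0 UMIs in 1 of the profiles, the median was also taken with such members at their bound. Of the later trophoblast list, 5 of the 13 members matched a symbol and at most 2 were measured in any comparison, so that no median was taken.

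For each pair of profiles, named genes are the 10 largest log2 ratios in each direction among genes with at least 100 CPM and 30 UMIs in the higher profile and detected in at least 10% of its cells, leaving out ribosomal, mitochondrial, predicted and haemoglobin genes and, within a library, the naming markers. Up to 4 members per list with the largest ratios, among those of at least 20 CPM, and Gata6, Cdx2, Eomes, Elf5, Xist and Tsix were added. Similarity between profiles is the Spearman correlation across genes of log2(CPM+1), over genes of at least 10 CPM in any profile without the naming markers, and contrasts between classes were compared by Pearson correlation over the same genes.

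Alternatives were run for doublet removal, cell filters, clustering resolution, variable genes, class assignment, the filter on low genes, the kind of correlation, the pseudocount, scaling, summing and depth. Alternatives for doublets, free RNA, shallow cells and naming were added after seeing the data. The ratios and list percentiles were tested on simulated data. With genes set 2-fold apart, 100% of PrE-like and 92% of EPI-like log2 ratios lay within 0.5 of the true value. At 16-fold this was 90% and 68%, and the 95% intervals held the true ratio for 97.5% and 95.5% of the altered genes. Of lists of 12 unaltered genes, 6% lay outside percentiles 2.5 to 97.5, and all 100 lists set 2-fold higher, drawn from the same altered genes, lay above 97.5. These counts were Poisson draws from the blastocyst profile of each class. They held no other difference between libraries and no shared variation within lists, so these tests cover counting error only. Simulated cells of the 3 blastocyst classes at embryoid depths were all given their own class (100%). They were drawn from the summed profile of each class, without variation within it, so this does not show how well real embryoid cells are named.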

Results

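The transcriptomes of single cells were measured in 1 embryoid library and 1 library from blastocysts of embryonic day 4.5, the stage at which the embryo consists of epiblast, primitive endoderm and trophectoderm. The embryoids were aggregates of ES cells, the cell culture counterpart of the epiblast, and XTE cells, which the study describes as trophectoderm-like. After filtering, 5324 of 5546 embryoid barcodes and 1080 of 1288 blastocyst barcodes were analysed. The median cell had 4768 UMIs and 2372 detected genes in the embryoid library and 9273 UMIs and 3293 genes in the blastocyst library. Intervals and floors below cover counting error only, and with 1 library per group a difference between libraries cannot be told apart from the difference between embryoid and blastocyst.

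Clusters of the blastocyst library took the names of all 3 lineages. PrE-like cells numbered 447, or 41.4% of the library (95% interval 38.4 to 44.4). TE-like cells numbered 376, or 34.8% (32.0 to 37.7), and EPI-like cells 257, or 23.8% (21.3 to 26.5). In the embryoid library 8 clusters were PrE-like and held 4698 cells, or 88.2% (87.3 to 89.1). EPI-like cells were 108, or 2.03% (1.67 to 2.44). A further 110 cells, or 2.07% (1.70 to 2.48), expressed Col1a1, Col3a1 and other fibroblast or extraembryonic mesoderm markers, and 408 cells, or 7.66% (6.96 to 8.41), stayed unnamed. No embryoid cluster was TE-like. The shares depended on the settings: the unnamed embryoid share ran from 0.0% to 31.7%, at the expense of the PrE-like share, and the FIB-like share was 7.10% with at least 2000 genes per cell. Keeping the barcodes called doublets, only 4 in the embryoid library, was enough to give a PrE-like share of 71.5%. The blastocyst TE-like share was 21.8% with at most 10% mitochondrial UMIs.

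**Figure D1:**
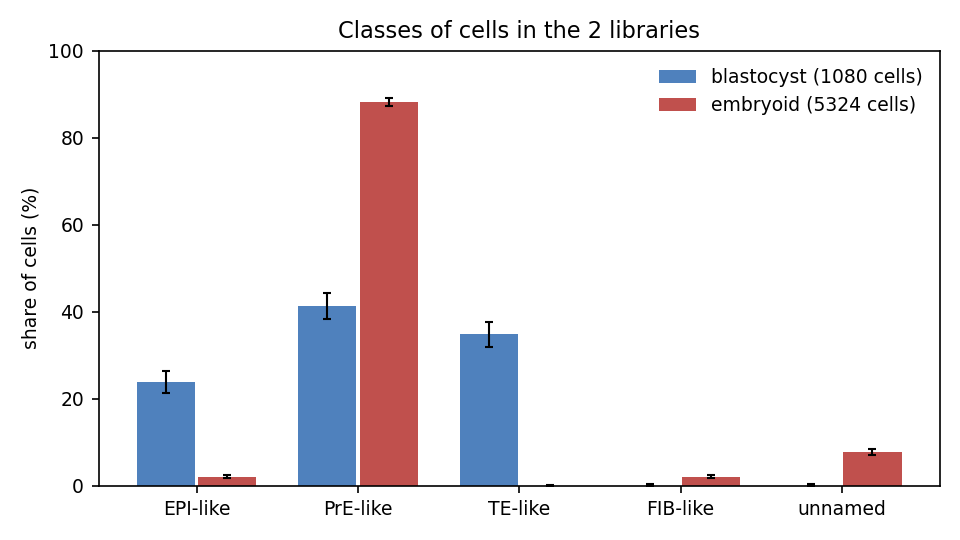
Share of cells per class in the blastocyst library (1080 cells) and the embryoid library (5324 cells), with exact 95% intervals. PrE-like cells made up 88.2% of the embryoid library and 41.4% of the blastocyst library.

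The lineages of the blastocyst were compared with one another first, since the series sets out to characterise them. TE-like cells exceeded EPI-like cells in epithelial genes. The claudins Cldn7 and Cldn4 and occludin (Ocln), proteins that seal tight junctions, stood at 644, 960.5 and 93.7 CPM against 24.7, 40.3 and 4.95 CPM. Of 16 measured tight junction and polarity genes, 11 were at least 2-fold higher in TE-like cells and 0 at least 2-fold lower. The list median was a log2 ratio of 2.07, at percentile 100 of matched random lists. The lineage that pumps fluid into the blastocyst cavity also had more RNA of the water channels Aqp9 (log2 ratio 4.88, 95% interval 4.37 to 5.95) and Aqp3 (1.29, 1.12 to 1.48), with a median of 0.87 for the fluid transport list (percentile 99.3).

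Apart from markers, the largest ratios towards TE-like cells belonged to BC051665 (9.08, 8.43 to 13.33), BC053393 (8.75, 8.24 to 9.93) and the imprinted noncoding RNA H19, with 1555 CPM against 5.33 (7.94, 7.44 to 9.06). Entpd1 and Enpp1, ectoenzymes that cleave nucleotides, were at least 182-fold and 178-fold higher, and the transcription factor Cebpa at least 129.5-fold. Psap, the precursor of the saposins of the lysosome, was at 6581 CPM against 251. Id2, a BMP target, was at 1744 CPM against 48.3, while the related Id3 was at 54.6 against 477. Genes of respiratory chain subunits stood slightly higher, with a median of 0.46 (percentile 99.5) and none of 20 members 2-fold apart.

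EPI-like cells exceeded TE-like cells in pluripotency genes and in signalling genes of the FGF and Nodal pathways. The naive pluripotency list had a median of -2.45 (percentile 0.0), with 7 of 13 members at least 2-fold lower in TE-like cells, among them Esrrb (13.9 against 358 CPM). Etv5, a transcription factor induced by ERK signalling, had 1.67 CPM against 299, and the FGF/ERK list a median of -2.26. Nodal had 0 UMIs in TE-like cells, at least 101-fold below its 84.5 CPM in EPI-like cells, and the list of its pathway had a median of -5.26. Trh, the precursor of thyrotropin-releasing hormone, stood lowest of all named genes at -8.62 (-16.12 to -8.33, 1 UMI in TE-like cells). DNA methylation genes were lower (median -1.88), with Tet1, which oxidises methylated cytosine, at 13.4 against 418 CPM. The S phase list (-1.52; 9 of 13 members at least 2-fold lower), the G2/M list (-0.81) and the glycolysis list (-0.80, percentile 2.05) also had negative medians, as did the basement membrane list (-1.72; 11 of 16). The median of ratios gave a shift of -0.30 for TE-like over EPI-like and of -0.33 for TE-like over PrE-like cells. Scaling subtracts this shift and so raises every TE-like ratio by its size, and these medians are to be read with that in mind.

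PrE-like cells were marked by the machinery of basement membrane production. Col4a1, a chain of the collagen of basement membranes, was at 2417 CPM against 30.4 in EPI-like cells (log2 ratio 6.27), and the laminin chain Lamb1 at 1586 against 36.1 (5.42). P4ha2, which hydroxylates collagen prolines, had a ratio of 7.01. Of 16 basement membrane genes 12 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 3.27 (percentile 100). The cathepsins Ctsl and Ctsz, proteases of the lysosome, were at 2229.8 and 205 CPM against 291 and 9.13, and the lysosome list had a median of 0.59 (percentile 99.7). Cholesterol synthesis genes had a median of 0.86 (7 of 15 at least 2-fold higher), with the sterol demethylase Cyp51 at 201 against 41.5 CPM. Foxq1 (1273 against 4.18 CPM), the adhesion protein Flrt3 (691 against 4.95), the Wnt antagonist Dkk1 (488 against 4.18) and the water channel Aqp8 (298.5 against 2.28) were among the named genes. Pth1r, the receptor for parathyroid hormone-related protein, was at least 131.5-fold higher. EPI-like cells held more Klf2 (855 against 14.3 CPM), a naive pluripotency factor, and Foxd3, at least 165.8-fold. The naive list had a median of -1.08 (percentile 0.0).

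Set against PrE-like cells, TE-like cells again had the tight junction genes (median 2.23; 10 of 16 at least 2-fold higher), with Cldn4 at 960.5 against 1.94 CPM. Their basement membrane genes stood far lower, with a median of -5.53 and 14 of 16 members at least 2-fold lower. Serpinh1, the collagen chaperone, was at 5.02 against 2786 CPM. The lists also parted in cholesterol synthesis (-1.09), amino acid stress (-0.99), G2/M phase (-1.09; Top2a 148 against 621 CPM) and oxidative phosphorylation (0.70; percentile 99.9). The 2 extraembryonic lineages used different water channels: Aqp9 was at least 269.8-fold higher in TE-like cells, and Aqp8 was at 1.95 against 298.5 CPM. Xist, the noncoding RNA that silences an X chromosome, was at 182 CPM in PrE-like, 142 CPM in TE-like and 3.04 CPM in EPI-like cells.

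The design then asks how embryoid cells compare with these lineages. The main body of embryoid cells, PrE-like in markers, was also closest to primitive endoderm in the genes that had not served for naming. Across 10179 genes its Spearman correlation was 0.798 with blastocyst PrE-like, 0.682 with TE-like and 0.663 with EPI-like cells, and each of the 8 PrE-like clusters had its highest correlation (0.742 to 0.819) with PrE-like cells. The unnamed clusters 7 and 11 and the FIB-like cells were also closest to PrE-like cells (0.741, 0.702 and 0.719). Being closest to PrE-like cells therefore does not set the PrE-like clusters apart from these. Embryoid EPI-like cells correlated at 0.861 with EPI-like, 0.797 with PrE-like and 0.667 with TE-like cells. The cells of a blastocyst class, split at random, correlated at 0.982 to 0.988, and genes are not independent replicates. The blastocyst classes themselves correlated at 0.837 (PrE-like with EPI-like), 0.785 (TE-like with PrE-like) and 0.731 (TE-like with EPI-like), so the embryoid PrE-like profile was less close to blastocyst PrE-like cells than blastocyst EPI-like cells were, and its values rank the classes without showing identity. Assigned cell by cell to the nearest blastocyst class, 5191 embryoid cells (97.5%) fell to PrE-like, 111 (2.08%) to EPI-like and 22 (0.413%) to TE-like. The measure also placed 101 of the 110 FIB-like (91.8%) and 392 of the 408 unnamed cells (96.1%) with PrE-like cells, so it does not tell such cells from primitive endoderm.

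**Figure D2:**
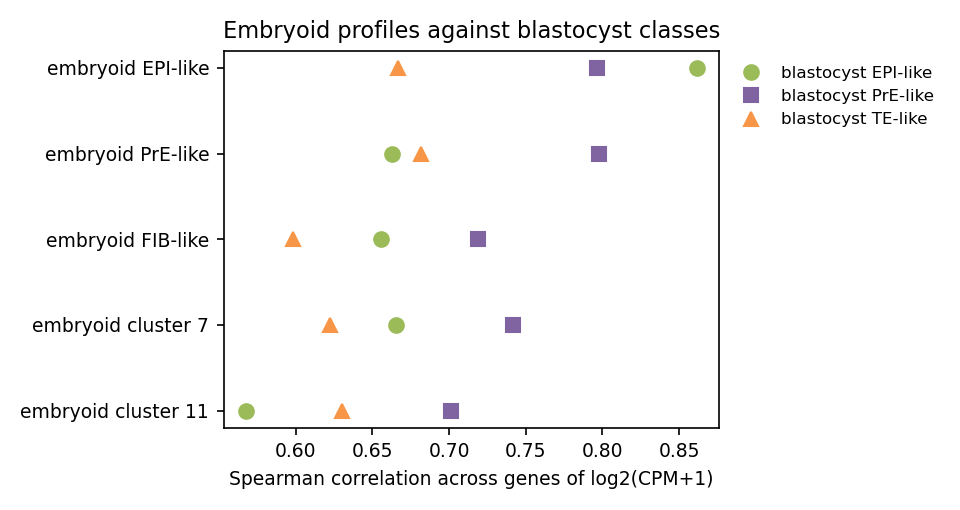
Spearman correlation across genes between each embryoid profile and the 3 blastocyst classes, without naming markers. Embryoid PrE-like cells lie at 0.798 for PrE-like against 0.682 for TE-like cells, and embryoid EPI-like cells at 0.861 for EPI-like cells.

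Transcription factors of trophectoderm were low in embryoid PrE-like cells. Cdx2, which specifies the lineage, was at 9.27 CPM (8.13 to 10.5) against 294 CPM in blastocyst TE-like cells. Eomes was at 12.1 against 467 CPM, Gata3 at 0.582 against 698 CPM and Elf5, a factor of trophoblast stem cells, at 0.194 against 228 CPM. Dppa1 had 0 UMIs against 1186 CPM, at least 10191-fold lower. The trophectoderm marker list had a median log2 ratio of -4.91, with 16 of 18 members at least 2-fold lower. These markers also served to name the clusters, so low levels of them in PrE-like clusters are in part built in. Among the markers, Krt18 and Krt8, keratins of simple epithelia, were far above their blastocyst PrE-like level: Krt18 was at 501 CPM against 2161 in TE-like and 7.76 in blastocyst PrE-like cells, and Krt8 at 129.9 against 262 and 3.64 CPM. Cdx2 (0.485 CPM in blastocyst PrE-like cells), Tspan8 (32.1 against 3.15) and Gata2 (15.3 against 2.18) also exceeded that level, though all 3 stayed far below TE-like cells. A further keratin, Krt7, was at 0.775 against 54.9 CPM in TE-like cells. Krt18 was seen in 81.6% of embryoid PrE-like cells (median 4843 UMIs) and in 13.0% of embryoid EPI-like cells (median 6345 UMIs). Cdx2 was seen in 4.73% and 2.78% of them, a difference that 108 EPI-like cells do not resolve.

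**Figure D3:**
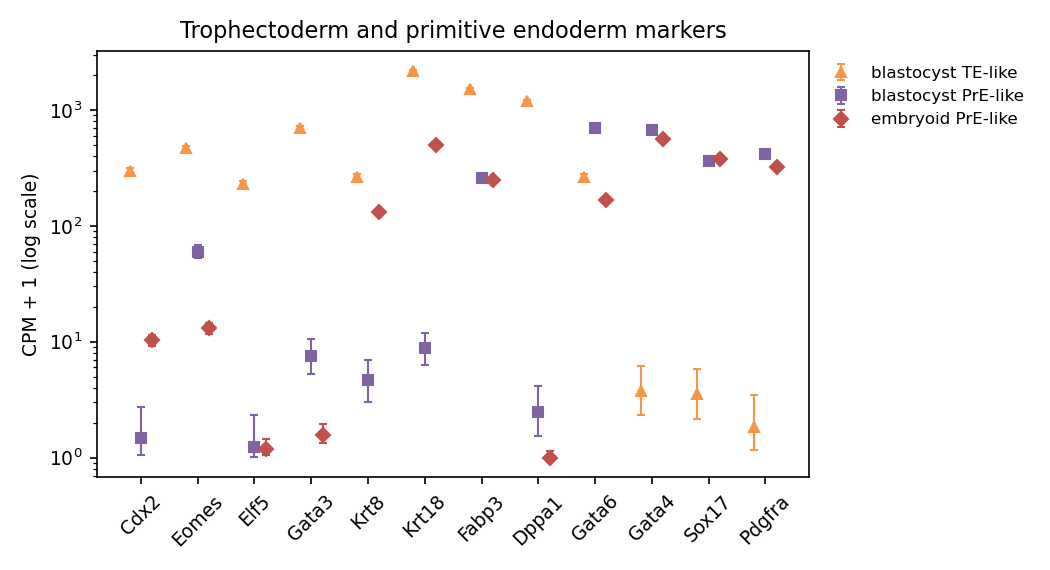
Levels of trophectoderm and primitive endoderm markers as CPM+1 on a log axis, with exact 95% intervals, in blastocyst TE-like, blastocyst PrE-like and embryoid PrE-like cells. Krt18 and Krt8 in embryoid cells (501 and 129.9 CPM) lie between the blastocyst classes, while Elf5 and Dppa1 lie at 0.194 and 0 CPM.

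Beyond the markers, embryoid PrE-like cells exceeded TE-like cells in basement membrane (median 4.98; 14 of 16 members at least 2-fold higher; Col4a1 4462 against 7.81 CPM), parietal endoderm (4.12), hypoxia (2.47), p53 target (2.60) and visceral endoderm genes (2.38). They were lower in oxidative phosphorylation (-0.98; 10 of 20 at least 2-fold lower) and slightly lower in tight junction genes (-0.42, percentile 1.93). On an axis from the PrE-like level (0) to the TE-like level (1) of the blastocyst, their median position was 0.123 over the 498 genes at least 4-fold higher in TE-like cells. Over the 840 genes at least 4-fold higher in PrE-like cells it was 0.0850. Of these genes, 140 and 199 lay nearer to the TE-like level. The contrast of PrE-like with EPI-like cells was compared between libraries, which removes what differs between libraries as a whole. It had a Pearson correlation of 0.568 across genes, and 83.4% of the 2624 genes at least 2-fold apart in the blastocyst had the same sign in the embryoid. The embryoid contrast correlated at 0.433 with the TE-like over EPI-like contrast, with the same sign at 72.0% of 3951 genes, and within the blastocyst the TE-like and PrE-like contrasts, which share EPI-like cells, correlated at 0.503.

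Embryoid and blastocyst PrE-like cells were then compared within the class. Most of the visceral endoderm genes stood higher in embryoid PrE-like cells. Rbp4, which carries retinol, was at 353 CPM against 0.243 (log2 ratio 8.15, 8.03 to 15.81, 1 UMI in the blastocyst profile). Ttr, a carrier of thyroid hormone and of Rbp4, was at 326.5 against 1.70 CPM (6.92, 6.54 to 8.90), and the calcium-binding S100g at 1419 against 31.8 CPM (5.44, 5.23 to 5.74). Of 14 visceral endoderm genes 10 were at least 2-fold higher and 1 at least 2-fold lower, and their median of 2.74 lay at percentile 100. With CPM+10, which shrinks the ratios of low genes, it was 0.88. The naming markers Cubn and Amn, which form the receptor for uptake in absorptive endoderm, went the other way, at 125 against 387 and at 149 against 550.0 CPM.

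Imprinted genes formed a further group with higher levels in the embryoid. The paternally expressed Peg10 was at 841 CPM against 0.485 (9.15, 8.91 to 13.80, 2 UMIs), the growth factor Igf2 at 2136 against 66.9 CPM (4.97, 4.83 to 5.17) and Sgce at least 171-fold higher. Among maternally expressed genes, H19 was at 734 against 41.2 CPM and the cell cycle inhibitor Cdkn1c at 71.2 against 1.46 CPM. The medians were 2.68 for the paternal list (9 of 13 at least 2-fold higher, 1 lower) and 2.20 for the maternal list (7 of 9 higher, 1 lower), both at percentile 100. Flt1, a receptor for VEGF, was at 1228 against 6.79 CPM (7.30, 6.97 to 8.09), the glypican Gpc3 at 1205 against 13.8 CPM, and Igfbp1 at least 514-fold higher.

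The lists of p53 targets, hypoxia, glycolysis and dissociation stress also stood higher in embryoid PrE-like cells. Targets of p53 had a median of 2.88 (percentile 100; 8 of 11 at least 2-fold higher, 0 lower), with the cell cycle inhibitor Cdkn1a at 456 against 7.03 CPM and Ccng1 at 671 against 56.5. Hypoxia genes had a median of 2.50 (8 of 10 higher, 1 lower), with the oxygen sensor Egln3 at 129.8 against 2.67 CPM and Bnip3 at 573 against 64.5. Glycolysis genes had a median of 1.14 (9 of 14 higher, 0 lower), led by the glucose transporter Slc2a1 (342 against 64.5 CPM) and Pgk1 (282 against 58.9). Immediate early genes, which respond to tissue dissociation, were higher as well (median 2.07; 8 of 11 higher, 1 lower), with Jun at 1626 against 19.4 CPM and Fos at 1202 against 22.3. Smaller positive medians at or above percentile 98.0 were those of tight junction (1.27; Cldn7 404 against 33.7 CPM), interferon and MHC class I (1.10; B2m 572 against 55.1), YAP target (0.79), BMP target (0.78; Id3 158 against 34.0), cholesterol synthesis (0.60) and lysosome genes (0.59; Ctsd 324 against 62.3). The Wnt target list had a median of 0.66 (percentile 93.6).

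Blastocyst PrE-like cells held what remained of naive pluripotency. Esrrb was at 144 CPM against 0.116 in the embryoid (-7.02, interval of the counts -12.55 to -8.72, 3 UMIs), Fbxo15 at 854 against 20.3 CPM, and Tcl1 was at least 1466-fold lower in the embryoid. The naive list had a median of -2.96 (percentile 0.0; 10 of 12 at least 2-fold lower, 0 higher). Dnmt3l, a cofactor of the de novo DNA methyltransferases, was at 408 against 0.465 CPM (-8.12), and Dnmt3b at 938 against 64.0. The growth factor Fgf10 (355 against 1.12 CPM) and the Nodal inhibitor Lefty2 (130.2 against 0.0776 CPM, 2 UMIs) were also far lower in the embryoid. Gata6, the tagged locus of the XTE line, was at 165 CPM (-2.09, -2.16 to -2.03) against 705, while Sox17 was at 376 against 364 and Gata4 at 558 against 669. Xist was at 0.504 against 182 CPM. Negative medians below percentile 5 came from amino acid stress (-1.03; Asns 156.5 against 453 CPM), DNA methylation (-0.89), Nodal pathway (-0.85), S phase (-0.47) and formative pluripotency genes (-0.42; -0.77 with members at 0 UMIs at their bound). Lists within the range of most random lists were fluid transport (0.01), FGF/ERK targets (-0.11), oxidative phosphorylation (-0.17), parietal endoderm (-0.21), basement membrane (-0.22) and G2/M phase (-0.23). Tsix was at 2.02 against 2.43 CPM.

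**Figure D4:**
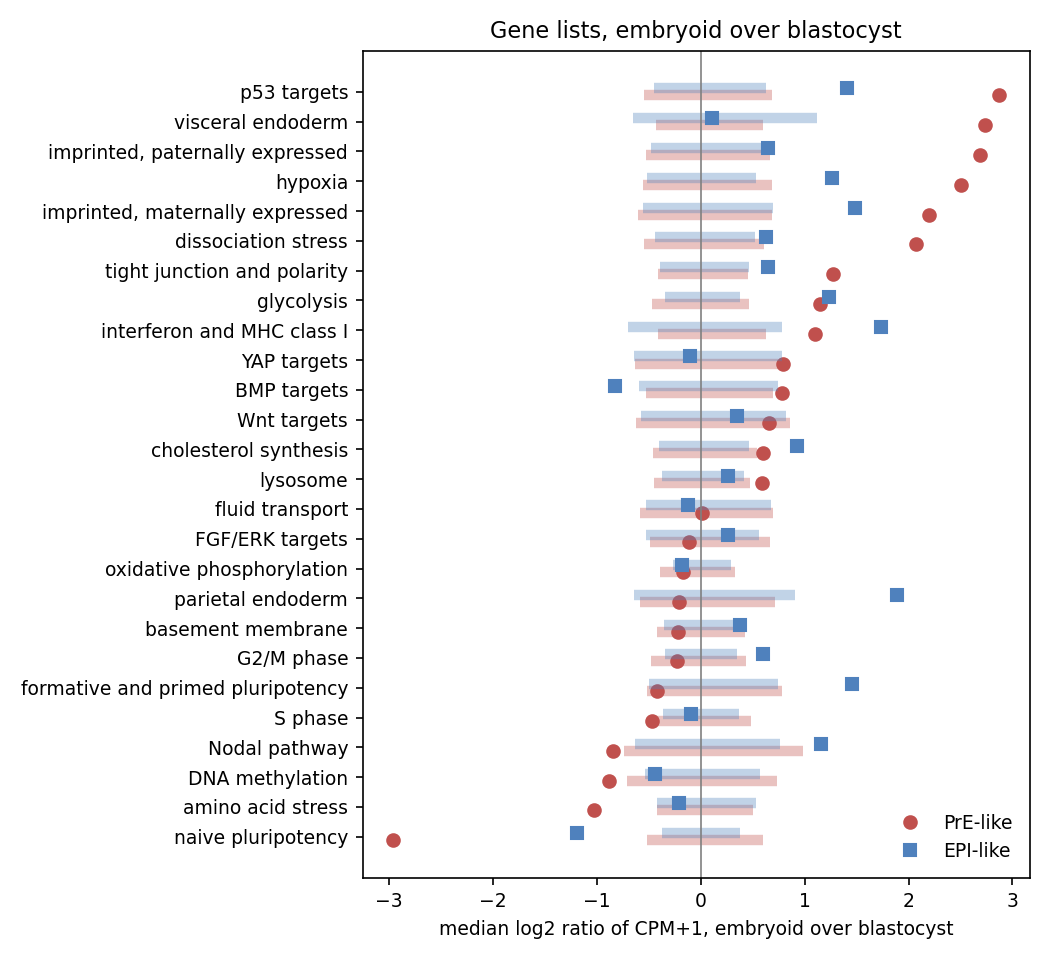
Median log2 ratio of embryoid over blastocyst for each gene list, in PrE-like cells (circles) and EPI-like cells (squares), with the 95% range of matched random lists as bars. In PrE-like cells p53 targets (2.88) and visceral endoderm genes (2.74) lie highest and naive pluripotency genes (-2.96) lowest.

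The order of these lists in PrE-like cells holds a part that is common to the library. Embryoid over blastocyst ratios in PrE-like and EPI-like cells correlated at 0.545 (Pearson, 9939 genes), with 260 genes at least 4-fold higher in both classes and 122 at least 4-fold lower in both. With the ratio in EPI-like cells subtracted from that in PrE-like cells gene by gene, the lists with the highest medians of this difference were visceral endoderm (2.38), tight junction (1.64), hypoxia (1.57), fluid transport (1.54) and dissociation stress (1.41). The lowest were the Nodal pathway (-2.01), naive pluripotency (-1.88), formative pluripotency (-1.59) and basement membrane (-1.50). The median was 0.70 for p53 targets, 0.12 for maternally expressed imprinted genes and -0.23 for glycolysis. The EPI-like ratios used here include the cells rich in PrE transcripts. Without those cells the EPI-like medians fell from 1.48 to 0.58 for the maternally expressed and from 0.65 to 0.08 for the tight junction list. They also fell from -0.13 to -0.75 for the fluid transport and from 0.38 to -0.33 for the basement membrane list. The direction of the G2/M list turned with the filters, and the Nodal list had 0.45 without members under 10 CPM.

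EPI-like cells were compared between the libraries in the same way, with 108 embryoid and 257 blastocyst cells. The embryoid cells had less of the naive and more of the formative pluripotency genes. Tfcp2l1 was at 70.8 against 433 CPM (-2.59, -3.04 to -2.21), Tbx3 at 70.8 against 407 (-2.50), Klf5 at 36.1 against 219.9 (-2.57) and Prdm14 at 9.72 against 84.1 CPM (-2.99). The naive list had a median of -1.19 (percentile 0.0), with 7 of 13 members at least 2-fold lower and 1 higher. Dnmt3a, a de novo DNA methyltransferase, was at 204 against 32.0 CPM (2.64, 2.28 to 3.08), Lef1 at 117 against 39.6 (1.54) and Otx2 at 355.5 against 148 (1.25, 1.03 to 1.49). Pou3f1, a POU factor of the formative state, had a ratio of 2.65 (1.79 to 4.19). The formative list had a median of 1.45 (percentile 99.98), with 8 of 11 members at least 2-fold higher and 0 lower. The blastocyst reference joined clusters 2 and 4. Cluster 4 differed from cluster 2 in the same direction in the naive, formative, glycolysis and hypoxia lists, as given under other observations. Embryoid cells were not compared with either cluster alone, so these differences are not shown to be particular to the embryoid.

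Genes of glycolysis, hypoxia and cholesterol synthesis and p53 targets were higher in embryoid EPI-like cells too. Ldhb, a subunit of lactate dehydrogenase, was at 165 against 4.18 CPM, and the glycolytic enzymes Pgk1 and Tpi1 had ratios of 2.52 and 2.38, with a list median of 1.23 (8 of 14 higher, 0 lower). Ankrd37 (2.20) and the pyruvate dehydrogenase kinase Pdk1 (1.94) led the hypoxia list, whose median was 1.27. Cdkn1a was at 224 against 32.7 CPM and Ccng1 at 296 against 47.9, and the p53 list had a median of 1.41 (percentile 100; 6 of 11 higher, 0 lower). Cholesterol synthesis genes (0.92), the Nodal pathway (1.16; Nodal 162.5 against 84.5 CPM) and G2/M genes (0.60) had positive medians above percentile 99. Imprinted transcripts Meg3 (2.40) and Rian (2.50) stood higher, in a maternally expressed list with a median of 1.48 (6 of 9 higher, 1 lower), and Peg10 was at 312 against 12.2 CPM (4.57). Bex4 (5.06) and the amino acid transporter Slc38a1 (4.37) were further named genes. Khdc3, an oocyte and early embryo gene, was at least 44.4-fold lower, Lgals3 at -4.68 (-6.79 to -3.54) and Aqp3 at -5.74 (-11.82 to -4.03, 1 UMI).

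The remaining lists were interferon and MHC class I (1.74), tight junction (0.65), paternally expressed imprinted genes (0.65), dissociation stress (0.63), basement membrane (0.38), Wnt targets (0.35), FGF/ERK targets (0.27), lysosome (0.26), visceral endoderm (0.10), S phase (-0.10), YAP targets (-0.11), fluid transport (-0.13), oxidative phosphorylation (-0.18), amino acid stress (-0.21), DNA methylation (-0.44) and BMP targets (-0.82). Primitive endoderm transcripts accompanied the embryoid EPI-like profile: PrE markers had a median of 2.15, the parietal endoderm list 1.88, S100g was at least 274-fold higher (8.29 as the log2 ratio of CPM+1), and Flt1, Igf2, Cited1 and Col4a2 had ratios of 5.83, 5.43, 4.97 and 4.15. Without the 20% of EPI-like cells richest in such transcripts, S100g was at 2.24 and the other 4 genes were at 2.51, 2.29, 0.85 and 1.56, Fosb at 3.37 in place of 4.83, and the parietal list at -0.02. Subtraction of free RNA turned the direction of Flt1 (-1.10), Cited1 (-1.87) and Col4a2 (-3.11). The amount subtracted was set from the level of the PrE markers in these cells, Cited1 among them. That counts all of this signal as free RNA, so lower levels of PrE genes were built in and tell nothing of the source. Without the cells richest in PrE transcripts the maternally expressed imprinted list was at 0.58, interferon and MHC class I at 1.00, dissociation stress at 0.11, tight junction at 0.08, basement membrane at -0.33, fluid transport at -0.75 and BMP targets at -1.68. Paternally expressed imprinted genes were then at 0.25, lysosome genes at -0.12, hypoxia at 0.85, Wnt targets at 0.20, FGF/ERK targets at 0.40, YAP targets at -0.23 and S phase at 0.02, while the naive list was at -1.07, the formative list at 1.55, the p53 list at 1.56 and the glycolysis list at 1.22.

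Within the embryoid library, PrE-like cells were set against EPI-like cells. Basement membrane genes were again the mark of PrE-like cells (median 2.42; 11 of 16 at least 2-fold higher, 1 lower), with the laminin chain Lama1 at 528 against 34.7 CPM (3.89). The visceral endoderm list had a median of 2.15 (1.91 with members at 0 UMIs at their bound), with Spink3 at 961 against 41.7 CPM. Lysosome genes (1.51; 11 of 14 higher, 0 lower), tight junction genes (1.35; 9 of 16 higher, 0 lower), hypoxia genes (1.16) and fluid transport genes (1.19) were higher as well. EPI-like cells had the naive (-4.28; 10 of 13 at least 2-fold lower in PrE-like cells, 1 higher) and formative genes (-2.65; 9 of 11 lower, 1 higher), and more of the S phase (-0.96), FGF/ERK (-1.05), DNA methylation (-1.18) and Nodal pathway lists (-1.68). Dnmt3l was at 615 CPM in them against 0.465, and Trh at 1309 against 2.91. H19 was at 734 CPM in PrE-like against 16.7 in EPI-like cells, and Amot, a junction protein of the Hippo pathway, at 210.3 against 5.55.

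The 8 PrE-like clusters of the embryoid differed from one another in lists of endoderm and cell cycle genes. Cluster 8 had fewer UMIs per cell, a median of 2022 against 4843 over all PrE-like cells. Most of its 10 leading genes were predicted genes (Gm and Rik names), so its values are the least certain of the 8. Visceral endoderm genes, left out of the clustering, were higher in clusters 3, 4 and 6 than in the other PrE-like clusters, with medians of 0.92, 0.88 and 1.05. They were lower in clusters 0, 1, 2, 5 and 8 (-1.19, -1.06, -1.40, -2.24 and -0.56; with members at 0 UMIs at their bound, -1.25 in cluster 2, -2.01 in cluster 5 and -0.33 in cluster 8). Spink3, a protease inhibitor of this list, was at 2109 CPM in cluster 6 against 820.2 in the others and at 44.1 in cluster 5 against 1065. Parietal endoderm genes had medians of 0.52 in cluster 0 and 0.57 in cluster 5, and of -0.88 in cluster 4 and -0.71 in cluster 6 (-0.70 and -0.47 at the bound). In clusters 1, 2, 3 and 8 they were at -0.14, -0.13, -0.26 and -0.23, so the lists did not part in every cluster. G2/M genes were higher in clusters 1, 2 and 4 (1.04, 1.00 and 0.94) and lower in clusters 0, 3, 5, 6 and 8 (-3.11, -2.05, -1.76, -2.45 and -0.34). FGF/ERK targets were higher in clusters 4 and 6 (0.85 and 0.81) and lower in clusters 0, 2 and 5 (-1.21, -1.56 and -1.60). YAP targets were higher in cluster 5 (0.78), with Ctgf at a ratio of 2.96.

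**Figure D5:**
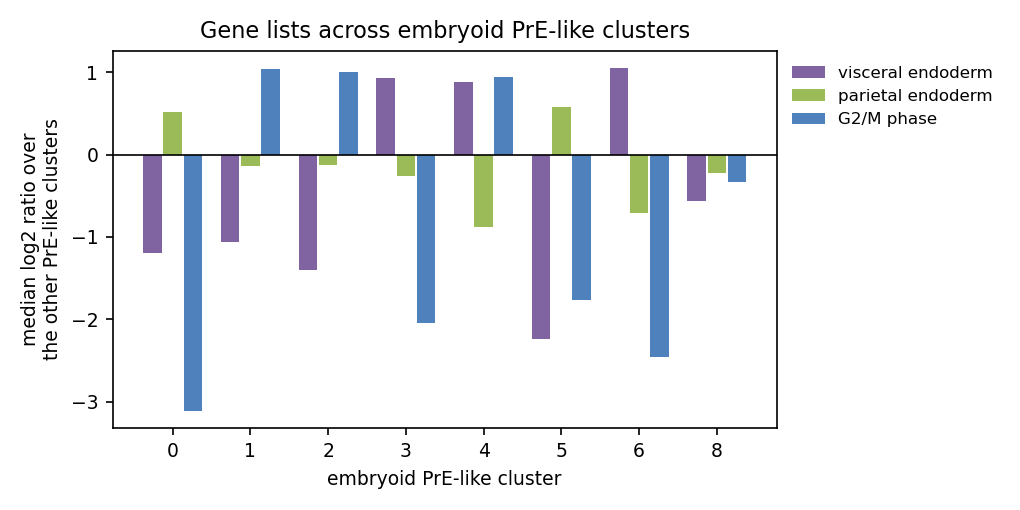
Median log2 ratio of 3 gene lists in each embryoid PrE-like cluster over the other PrE-like clusters. The visceral endoderm list is positive in clusters 3, 4 and 6 (0.92, 0.88 and 1.05) and reaches -2.24 in cluster 5, where the parietal endoderm list is at 0.57.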

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

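Both tests on the first group of cells below were chosen after the result was seen. In the embryoid library 326 cells, or 6.12%, formed cluster 7, which took no class name. The best class was primitive streak or mesoderm, with 2 of 4 detected markers high, under the minimum of 3. The collagen markers Col1a1, Col1a2 and Col3a1 were at 281, 136 and 316 CPM in cluster 7. They were at 621, 705 and 1631 CPM in FIB-like and at 0.737, 2.52 and 0.853 CPM in PrE-like cells. They were seen in only 15.0%, 13.2% and 29.8% of cluster 7 cells, against 33.6%, 56.4% and 80.9% of FIB-like cells. The PrE marker Gata4 was seen in 46.6% of cluster 7 cells and 88.7% of PrE-like cells. Summed levels therefore do not describe every cell of cluster 7. Against PrE-like cells its lists of BMP targets (1.85; 9 of 10 at least 2-fold higher) and FGF/ERK targets (1.70; 9 of 10) had high medians and tight junction genes a low one (-2.46; 13 of 16 at least 2-fold lower), with vimentin (Vim) at 2993 against 26.1 CPM. The tests argue against doublets or mixed RNA of the named embryoid classes as the source: 18 genes, among them Eomes, Sox9 and Tnc, were at least 4-fold above their highest level in any other embryoid cluster, and the median UMI count was 0.883 of that of PrE-like cells, where doublets would have more. No biological explanation was tested, and the origin of these cells stays open.

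A further embryoid cluster without a name, cluster 11, held 82 cells, or 1.54% (95% interval 1.23 to 1.91), with a median mitochondrial share of 0.193%, low G2/M genes (median log2 ratio over PrE-like cells -2.78) and higher p53 targets (1.06). Among the 191 blastocyst barcodes that the limit on mitochondrial UMIs left out, 156, or 81.7% (75.4 to 86.9), were nearest to the TE-like profile, at a median of 81 non-mitochondrial UMIs.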

How the results depend on the processing

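The removal of the 5% highest Scrublet scores, of cells over 3 times the median UMIs and of EPI-like cells rich in PrE transcripts, the subtraction of free RNA, the exclusion of shallow cells and the naming without exclusions were alternatives chosen after seeing the data. No paired analysis was possible because each group had 1 library. No reclustered setting gave a TE-like embryoid cluster, and in every setting with similarity run the embryoid PrE-like and EPI-like profiles stayed closest to their own blastocyst class. Over all alternatives, 1075 list medians stayed within their interval, 113 moved out of it and 6 reversed. This interval ran from the median of the members' lower limits to the median of their upper limits, so it is not a counting interval of the median itself. Medians that stayed could still differ, as that of tight junction genes in EPI-like cells did without the cells richest in PrE transcripts (0.08 in place of 0.65). Of those that stayed or moved, some changed sign where the interval spanned 0. Of single genes 459 stayed, 338 moved and 3 reversed.

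The embryoid PrE-like share was 71.5% with doublets kept, 73.8% with at least 2000 genes, 61.5% with at most 10% mitochondrial UMIs, 64.3% and 80.9% at Leiden resolution 0.5 and 2.0, 89.8% with 4000 variable genes including the lists, 71.4% without the top Scrublet scores, 70.1% without cells over 3 medians, 89.8% with the best class given to every cluster and 97.5% by the nearest blastocyst class. In the same order, up to the best class, the unnamed share was 18.3%, 16.6%, 27.9%, 31.7%, 14.9%, 0.0%, 19.1%, 25.8% and 0.0%. The best class of every cluster gave a PrE-like share of 89.4% to 90.6% in all reclustered settings, so that the lower shares come from clusters left unnamed. In all these settings except 4000 variable genes, 1 or 2 embryoid clusters stayed unnamed because their leading genes held more markers of another class. Whether the cells of those clusters are primitive endoderm was not tested. With at least 2000 genes the EPI-like share was 2.48% and the FIB-like share 7.10%. The nearest class gave a TE-like share of 0.413%. In the blastocyst, at most 10% mitochondrial UMIs gave 27.0% EPI-like, 51.2% PrE-like and 21.8% TE-like cells. The median mitochondrial share was 12.3%, 11.3% and 9.36% in TE-like clusters 1, 5 and 6. It was 9.69% and 7.93% in PrE-like clusters 0 and 3, and 10.5% and 8.62% in EPI-like clusters 2 and 4. The limit thus left out most cells of TE-like clusters 1 and 5. Resolution 2.0 gave 31.1% EPI-like, 29.1% PrE-like and 5.0% unnamed cells, and the cause was not tested.

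The margin of embryoid PrE-like cells (PrE-like over TE-like correlation, 0.116) was 0.113 with doublets kept, 0.1199 at resolution 2.0, 0.156 over genes of at least 50 CPM, 0.0561 without a filter on low genes and 0.134 as Pearson correlation. That of EPI-like cells (EPI-like over PrE-like, 0.0648) was 0.0673 with at most 10% mitochondrial UMIs, 0.0715 at resolution 2.0, 0.1203 over genes of at least 50 CPM, 0.0149 without a filter and 0.0698 as Pearson correlation. The PrE-like over EPI-like contrast correlated between libraries at 0.633 over genes of at least 50 CPM, 0.476 without a filter, 0.539 as Spearman correlation and 0.578 with CPM+10. The cause was not tested.

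For embryoid over blastocyst PrE-like cells, the visceral endoderm median was 0.88 with CPM+10, which shrinks ratios of low genes by construction, and 2.31 at resolution 0.5. The hypoxia median was 2.05 with CPM+10. The G2/M median (-0.23) reversed to 0.0155 with doublets kept, 0.0875 with at least 2000 genes, 0.0581 at resolution 0.5 and 0.0259 without cells over 3 medians. The Nodal median (-0.85) reversed to 0.45 without members under 10 CPM, by the loss of members. In EPI-like cells, subtraction of free RNA reversed Flt1 to -1.10, Cited1 to -1.87 and Col4a2 to -3.11. Its amount was set from the PrE markers, so that lower levels of PrE genes are built in. Leaving out the cells richest in PrE transcripts reversed the parietal endoderm median to -0.0161. The cause of the other reversals was not tested. Depth sets what a gene at 0 UMIs can mean: the floor was 4.17 CPM in embryoid EPI-like cells (720139 UMIs), 6.68 CPM in FIB-like cells (449401) and 1.14 CPM in blastocyst EPI-like cells (2628597). Thinned to 2000 UMIs per cell, 4992 embryoid and 1022 blastocyst cells remained.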

Other observations

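The tests in this part were chosen after the result was seen, except those of depth and of filters on the absent TE-like cluster and the first search for single cells of that kind; the control for grouping by library was also chosen after.

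Blastocyst classes held clusters that differed in lists of cell cycle, metabolic, pluripotency and visceral endoderm genes. Among EPI-like cells, cluster 4 (84 cells) had more of the formative genes than cluster 2 (173 cells), with a median log2 ratio of 1.03 (5 of 10 at least 2-fold higher; Lef1 94.5 against 3.16 CPM) and fewer naive genes (-0.76; Prdm14 24.8 against 123 CPM). The same cluster had higher glycolysis (1.35; Ldha 689 against 78.4 CPM) and hypoxia genes (1.02; Bnip3 138 against 36.7 CPM), and Tet2 at 44.9 against 290.3 CPM. Among PrE-like cells, cluster 3 (102 cells) exceeded cluster 0 (345 cells) in visceral endoderm (1.23; Spink3 ratio 3.18), glycolysis (1.02), hypoxia (0.92) and cholesterol synthesis genes (0.85). Within TE-like cells, cluster 5 (81 cells) had far lower G2/M (-2.65; 15 of 15 at least 2-fold lower), S phase (-1.43) and cholesterol synthesis genes (-2.05) than cluster 6 (74 cells), and H19 at 48.1 against 3672 CPM. Cluster 1 (221 cells) had lower glycolysis (-1.21) and amino acid stress genes (-1.65) than cluster 6.

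The 110 FIB-like cells of the embryoid exceeded PrE-like cells in Wnt targets (1.84; Nkd1 296 against 4.19 CPM), BMP targets (1.43; Msx1 147 against 4.69 CPM) and interferon and MHC class I genes (1.58; Ifit1 109 against 0.543 CPM). Paternally expressed imprinted genes stood higher in them (1.25; Dlk1 986 against 17.8 CPM), and tight junction genes lower (-2.09). Their profile correlated at 0.719 with blastocyst PrE-like, 0.655 with EPI-like and 0.598 with TE-like cells.

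The embryoid library had no TE-like cluster. The filters are argued against as the cause, since the 218 left-out barcodes held 51 UMIs of 14 TE markers among 94341, a median of 0.0% of the TE-like level. Low depth stays open: 53 blastocyst TE-like cells thinned to 4000 UMIs and added to the library fell in a TE-like cluster (100%), but of 53 blastocyst PrE-like cells added alike, 0 joined clusters mostly of embryoid cells, so added cells group by library and this test decides nothing. Single cells of the class hidden in other clusters stay open: 35.2% of embryoid cells had UMIs of 3 or more of the 14 markers (33.9 to 36.5), against 8.22% to 14.2% of blastocyst PrE-like cells (95% interval), but Krt8, Krt18 and Fabp3 reached 45.3%, 21.3% and 15.2% of the TE-like level over the whole library, so this measure cannot decide. Only 2 of the markers, Elf5 and Dppa1, stayed under 0.2% of the TE-like level over the whole library, fewer than the 3 set as needed to exclude a share above 0.2%.

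Embryoid EPI-like cells held primitive endoderm transcripts. Of the UMIs of 49 PrE genes in these cells, 79.6% lay in the 22 cells richest in them, where free RNA would spread over all cells, so that free RNA as the main source is argued against. Those 22 cells had a median of 9088 UMIs against 6085 in the others, a ratio of 1.49, and their epiblast markers were at 67.4% of the level in the others, which is consistent with doublets of an EPI-like and a PrE-like cell. No biological explanation was tested, and cells between the states stay open.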
